A study of Homo sapiens with 40 samples.

How the data were processed

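RNA was measured in spheroids of FaDu and Kyse30 cells carrying Dendra2, a fluorescent protein that light converts from green to red. Per the labels' protocols, spheroids were embedded in type I collagen and kept for 72 h in serum-free medium, in medium with 9 nM epidermal growth factor (EGF), in EGF with 10 µg/mL cetuximab, or in EGF with 100 nM of the MEK inhibitor AZD6244. Invasive areas were photoconverted, the collagen was digested with collagenase, and cells were sorted. Libraries were made with the Lexogen QuantSeq 3' mRNA-Seq V2 kit, which reads the 3' ends of polyadenylated transcripts, so a gene's count does not grow with transcript length. Unique molecular identifiers are not named in the labels, so p-values, intervals and floors cover counting error and the spread between libraries and not duplicated reads.

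The authors deposited 1 table of whole-number read counts per gene, with no normalization, for 12655 genes and 40 libraries. Alignment and counting used STAR and HTSeq on GRCh38, per the submitters' processing notes, whose versions, annotation and strand setting are not given in the sources used here. The table holds a preselection of genes whose rule is not stated. The smallest total of a listed gene over all libraries was 142 counts and the fewest libraries with a count was 4. Matched by symbol to the RefSeq gene table of the reference, 11336 of the genes were protein coding, 567 were long non-coding RNAs, 624 were pseudogenes and 106 had no match. Reads of near-identical genes can be split or lost by such counting, so values of pseudogenes and their parent genes are uncertain. A gene and an antisense partner were not told apart here because the strand setting is unknown.

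Each column name matched 1 sample description, and 0 columns were left unmatched. Groups were taken from the sample titles, which give 5 groups of 4 samples in each cell line. Titles call both the invasive and the non-invasive cells photoconverted, whereas the protocol names invasive areas. A separate label on cell selection describes photoconverted invasive cells for both the invasive and the non-invasive samples, so the division between these groups rests on the titles, with which the sample descriptions and column names agree. The same label calls the serum-free, cetuximab and MEK inhibitor samples unselected. No label says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom of 2.42 to 67.4.

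Total counts per library ran from 2312126 to 5669262 in FaDu and from 463124 to 4534339 in Kyse30. The library with 463124 counts, the first invasive replicate of Kyse30, was the only library under 1/3 of its cell line's median total. For each Kyse30 comparison the number of changed genes is given with and without it. Other Kyse30 values come from all libraries of the line unless stated.

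The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM normalization, edgeR's default expression filter by group and robust dispersion estimation. All 20 libraries of a cell line entered 1 fit, so that the 5 groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, 12131 in FaDu, 11976 in Kyse30 and 12072 in Kyse30 without its shallow library. Genes with an adjusted p under 0.05 are described as called, higher or lower. Fold changes are log2 values with their standard errors (SE) and keep their sign where a fall is described. Levels are CPM, counts scaled to a common library size with TMM factors, given as mean ± SD over 4 libraries. Where a group held 0 counts of a gene, the fold is a lower bound computed against a floor of 3 counts over the group. Differences between the cell lines were tested as interaction contrasts, the Kyse30 effect minus the FaDu effect, in 1 fit over all 40 libraries and again over 39.

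On simulated counts drawn from the means and library sizes of these samples, the test of invasive against non-invasive cells recovered 56.6% of genes changed 2-fold and 85.9% of genes changed 4-fold in FaDu. In Kyse30 it recovered 17.5% and 77.8%, and without the shallow library 31.3% and 73.7%. The interaction test for that comparison recovered 12% and 64%.

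A set of 30 gene lists was written from general knowledge before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternatives. The lists were partial epithelial-mesenchymal transition (EMT) markers, EMT transcription factors and mesenchymal genes, epithelial junction genes, ERK pathway output and feedback, the EGFR family with its ligands and feedback genes, AP-1 and immediate early genes, laminin-332 with integrins and hemidesmosome genes, matrix proteases and inhibitors, actin and motility genes, YAP/TEAD targets, TGF-beta response, G2/M genes, DNA replication genes, hypoxia response, glycolysis enzymes, squamous differentiation, basal keratinocyte genes, stress keratins and alarmins, interferon response, NF-kB cytokines and chemokines, cholesterol synthesis, integrated stress and unfolded protein response, heat shock, p53 targets, mitochondrially encoded mRNAs, ribosomal proteins, and markers of fibroblasts, leukocytes, endothelial cells and erythrocytes. Each list was counted by its called members and tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, with adjustment over the lists of a comparison. Where a Kyse30 list is given with and without the shallow library, the adjusted p with an estimated correlation was smaller without it. Lists of fewer than 5 tested genes got no set test.

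Genes were named by a fixed rule. Per cell line and comparison, the rule took called genes whose 4 libraries of 1 group all lay above the 4 of the other, with a mean of at least 10 CPM in the higher group and a gene symbol. Of these it took the 10 highest and 10 lowest fold changes for invasive against non-invasive cells, 6 and 6 for the other comparisons, and 5 and 5 for the interactions without the condition on libraries. It also took the 10 genes with the largest smallest fold change among those higher in invasive cells than in each other group and among those called in both lines, up to 4 members of each list with the smallest p, and EGFR, DUSP6, SPRY4 and PHLDA1, among others, in every group. Some of the genes taken are not reported here.

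Alternatives were DESeq2 size factors within edgeR, DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a stricter filter (at least 5 CPM in at least 4 libraries), the replicate number as a block, 1 fit over all 40 libraries, a fit of the compared groups alone, the shallow library left out, and each replicate left out in turn. A fit without 6 libraries, taken on inspection to stand apart, was added after the data were seen. In FaDu they were invasive replicate 2, cetuximab replicate 2 and MEK inhibitor replicate 1. In Kyse30 they were invasive replicate 1 and non-invasive replicates 1 and 3. Genes higher in both lines were tested against independent lists with a one-sided Fisher's exact test. Comparisons that share libraries were set beside 10 simulations of unchanged groups, beside the overlap expected of independent lists, and beside a fit with the shared libraries divided between the comparisons. Tables were drawn up in R and Python 3.11.15 and plots with matplotlib 3.10.9.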

Results

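The series addresses how EGF receptor signalling drives local invasion of head and neck cancer cells and how they respond to cetuximab. Polyadenylated RNA was counted in spheroids of 2 human squamous carcinoma cell lines grown in type I collagen. FaDu comes from a hypopharyngeal tumour and Kyse30 from an oesophageal squamous cell carcinoma. In each line 5 groups of 4 samples were compared. These were serum-free spheroids, non-invasive and invasive cells sorted from EGF-treated spheroids, spheroids given EGF with cetuximab, an antibody that blocks the EGF receptor, and spheroids given EGF with AZD6244, an inhibitor of the kinase MEK. Libraries held 2312126 to 5669262 counts in FaDu and 2538447 to 4534339 in Kyse30, apart from the first invasive Kyse30 replicate with 463124 counts.

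Levels of genes chosen in advance followed the treatments in FaDu. DUSP6, a phosphatase induced by and acting on ERK, stood at 9.74 ± 2.43 CPM (SD, n = 4) in serum-free spheroids, 427 ± 65.5 CPM in non-invasive and 398 ± 133 CPM in invasive EGF-treated cells, 104 ± 36.6 CPM with cetuximab and 9.68 ± 3.91 CPM with the MEK inhibitor. PHLDA1, another gene downstream of ERK, stood at 34.9 ± 7.47, 545 ± 124, 500.2 ± 128, 262 ± 50.4 and 27.9 ± 7.01 CPM in the same order. SPRY4, a feedback inhibitor of the pathway, had 0 counts in serum-free FaDu and 8.93 ± 3.02 CPM in non-invasive cells, at least 42.2-fold higher. EGFR itself stood at 1427 ± 67.2 CPM in serum-free spheroids, 555 ± 41.1 CPM in non-invasive cells, 538 ± 101 CPM with cetuximab and 997 ± 121 CPM with the MEK inhibitor.

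In Kyse30 the range was narrower for DUSP6, from 47.7 ± 9.49 CPM without serum and 92.1 ± 11.4 CPM in non-invasive cells to 118 ± 70.7 CPM with cetuximab and 22.9 ± 7.53 CPM with the MEK inhibitor. In the same order PHLDA1 stood at 300 ± 13.5, 493 ± 121, 350 ± 105 and 186 ± 40.0 CPM. SPRY4 stood at 6.49 ± 3.01, 9.88 ± 2.92, 7.73 ± 1.27 and 1.16 ± 0.533 CPM. EGFR stood at 3503 ± 105, 2120 ± 331, 2072 ± 395 and 2362 ± 524 CPM. Mitochondrial transcripts took 15.3% of the counts in serum-free FaDu and 8.38% to 11.4% in the other FaDu groups, and 22.0% in serum-free Kyse30 against 11.5% to 15.8% in the others. The shares of invasive and non-invasive cells were 11.4% and 9.37% in FaDu and 15.8% and 13.5% in Kyse30, where the invasive mean was 12.2% without the shallow library. Of the non-invasive Kyse30 libraries, replicates 1 and 3 had 6.27% and 9.63% of their counts in the nuclear RNA MALAT1, and replicates 2 and 4 had 1.68% and 1.91%. Mitochondrial transcripts took 17.4% and 19.3% in replicates 1 and 3, against 8.22% and 8.95% in replicates 2 and 4.

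**Figure D1:**
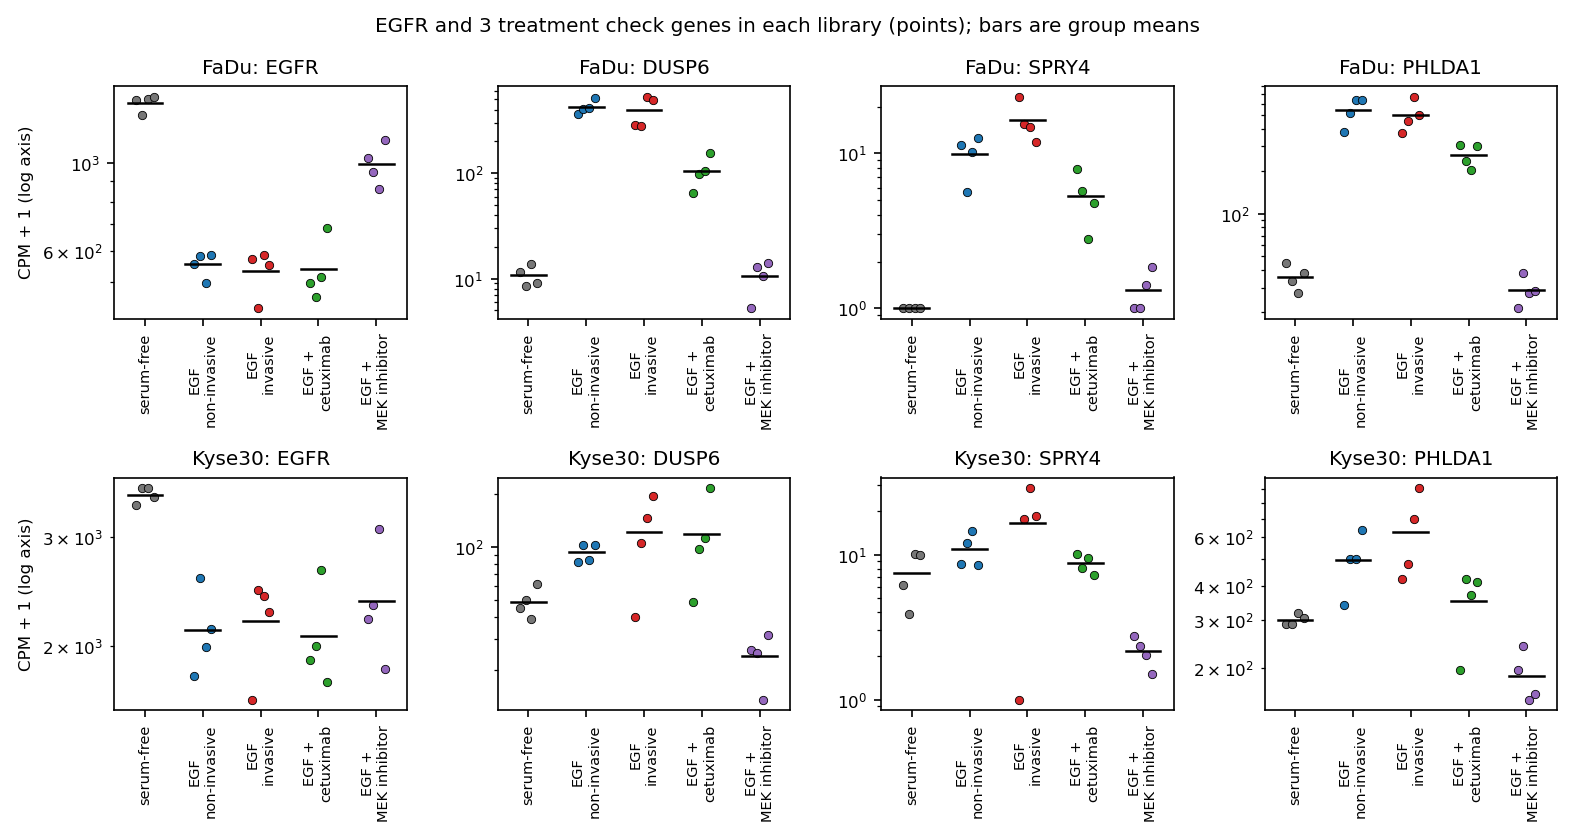
CPM + 1 on a log axis of EGFR and 3 other genes chosen in advance, with a point per library and a bar at the mean of 4 libraries for each group and cell line. In FaDu the mean of DUSP6 went from 9.74 CPM without serum to 427 CPM in non-invasive EGF-treated cells and 9.68 CPM with the MEK inhibitor.

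**Figure D2:**
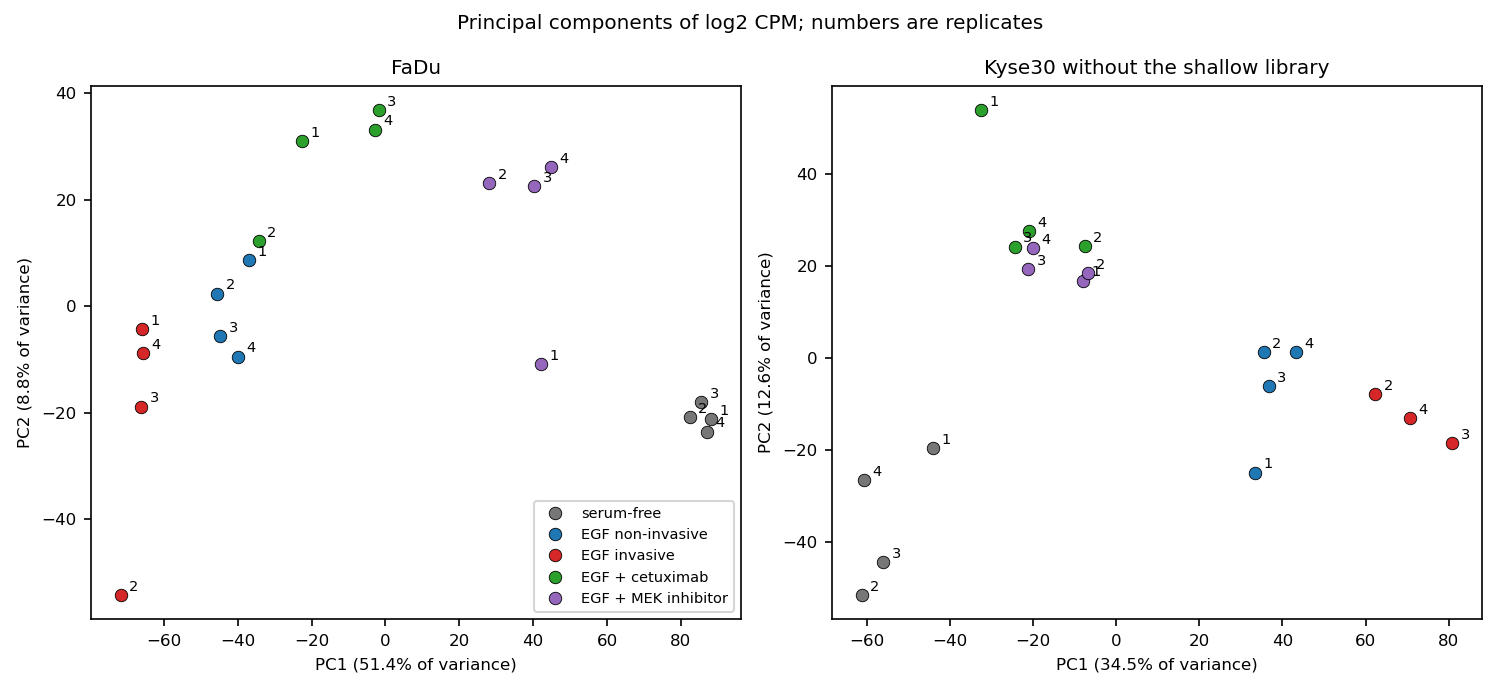
Principal components of log2 CPM within each cell line, with a point per library coloured by group and axes in units of component score with their percent of variance. In FaDu the first component held 51.4% of the variance and the second 8.81%.

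Between invasive and non-invasive cells of EGF-treated FaDu spheroids, more of the genes called were lower than higher in invasive cells. Lower genes included NDRG1, by -1.92 ± 0.29 log2 units (SE), the mitophagy receptor genes BNIP3 and BNIP3L at -1.84 ± 0.28 and -1.91 ± 0.23, and EGLN3, an oxygen-sensing hydroxylase, at -2.71 ± 0.49. The glycolytic enzymes ENO2, ALDOC and GPI changed by -2.40 ± 0.26, -1.41 ± 0.21 and -0.74 ± 0.13, and the lactate exporter SLC16A3 by -1.67 ± 0.21. Interferon-induced ISG15 and IFI27 fell by -1.41 ± 0.24 and -2.38 ± 0.48. The tight junction gene CLDN1, the collagen chain COL5A1 and the sodium channel subunit SCNN1A changed by -2.77 ± 0.55, -3.22 ± 0.44 and -2.45 ± 0.35.

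Genes higher in invasive FaDu cells included HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, at 1.34 ± 0.26 log2 units, the export pump ABCC2 at 1.40 ± 0.32 and the cystine transporter SLC7A11 at 0.90 ± 0.12. TONSL, which acts in repair at replication forks, rose by 1.75 ± 0.36, the mitotic motor KIF18A by 0.97 ± 0.25, RGS2, a regulator of G protein signalling, by 1.01 ± 0.24 and the microtubule-binding protein gene NAV3 by 0.91 ± 0.25. The pseudogenes KRT18P10, YBX1P10, NPM1P39 and SERBP1P1 were also among the 10 highest. Of the G2/M genes AURKA and CKAP2 rose, by 0.63 ± 0.16 and 0.48 ± 0.14.

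In all, 364 of the 12131 genes tested in FaDu were called between invasive and non-invasive cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 80 higher and 284 lower, and limma-voom called 364 higher and 420 lower. With a library of either group left out in turn 209 to 331 were called, and 84 in a single fit over all 40 libraries, 1 of them higher. Of the hypoxia response list 0 genes rose and 7 of 18 fell, 10 adjusted over the list alone, with a median of -0.88 log2 units (camera adjusted p = 1.5e-11, adjusted p = 0.13 with an estimated correlation). Of the glycolysis enzymes 8 of 17 fell, 10 adjusted over the list alone (camera adjusted p = 1.3e-08, adjusted p = 0.13 with an estimated correlation). Of the interferon response genes 9 of 22 fell, 18 adjusted over the list alone, with a median of -1.57 (camera adjusted p = 6.6e-13, adjusted p = 0.13 with an estimated correlation). Of the epithelial junction genes 4 of 23 fell, 8 adjusted over the list alone, including CDH3 and DSC2 at -0.63 ± 0.13 and -0.59 ± 0.15 (camera adjusted p = 2.9e-04, adjusted p = 0.13 with an estimated correlation). Of the G2/M genes 2 of 20 rose, 4 adjusted over the list alone (camera adjusted p = 4.9e-05, adjusted p = 0.27 with an estimated correlation). The heat shock list went both ways, with HSPB1 at -1.10 ± 0.13 and HSPD1 and HSP90AB1 at 0.51 ± 0.12 and 0.50 ± 0.13, 2 of 11 higher and 1 lower (5 and 1 adjusted over the list alone). The p53 targets GDF15 and BBC3 fell, by -2.12 ± 0.35 and -2.40 ± 0.55, 2 of 15 in that list and as many adjusted over the list alone. Invasive FaDu libraries held fewer detected genes, 11963 ± 247 against 12313 ± 19.8. Without the 6 libraries that stood apart, 704 genes were called.

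Invasive Kyse30 cells had higher levels of FERMT1, which encodes the integrin activator kindlin-1, by 2.20 ± 0.28 log2 units (SE). The tryptophanyl-tRNA synthetase WARS1 rose by 2.69 ± 0.47, ornithine decarboxylase ODC1 by 1.48 ± 0.34 and the interleukin-33 receptor gene IL1RL1 by 1.44 ± 0.31. Lower in invasive Kyse30 cells were the membrane mucins MUC20 and MUC15, by -3.18 ± 0.51 and -2.44 ± 0.52, the iron-binding lipocalin LCN2 by -3.57 ± 0.80, VTCN1, an immune checkpoint ligand, by -2.61 ± 0.35, and POU2F3, a transcription factor of tuft cells, by -2.48 ± 0.52. Without the shallow library the collagenase MMP1 was higher by 3.64 ± 0.83, the stromelysin MMP10 by 2.32 ± 0.62, keratin KRT6A by 2.29 ± 0.50 and the peripheral myelin protein gene PMP22 by 3.06 ± 0.66.

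Of 11976 genes tested in Kyse30, 49 were called between invasive and non-invasive cells by edgeR's quasi-likelihood test, 8 higher and 41 lower. Without the shallow library 253 were called, 88 higher and 165 lower, and with another library of either group left out in turn 7 to 73. In the fit without the shallow library 4 of 28 partial EMT markers rose and 0 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.099 with an estimated correlation). Of the laminin-332 and integrin list 4 of 16 rose, 7 and 1 lower adjusted over the list alone, with ITGA2, ITGA6 and LAMA3 at 1.04 ± 0.18, 1.14 ± 0.20 and 1.43 ± 0.26 (camera adjusted p = 4.1e-05, adjusted p = 0.12 with an estimated correlation). Of the DNA replication genes 4 of 20 rose, 13 adjusted over the list alone, with CDC6 and RRM2 at 1.19 ± 0.28 and 1.24 ± 0.31 (camera adjusted p = 6.6e-12, adjusted p = 0.099 with an estimated correlation). The hypoxia list had 1 of 18 higher, 2 adjusted over the list alone, and a median of 0.31 (camera adjusted p = 0.0044, adjusted p = 0.25 with an estimated correlation). In the fit with all 20 libraries these lists had 1, 1, 0 and 0 members called higher and estimated-correlation adjusted p of 0.57, 0.57, 0.64 and 0.78. Fry in that fit gave an adjusted p of 0.97 for each of them, and its direction was lower for the DNA replication and hypoxia lists. The mean share of MALAT1 was 3.93% in invasive (2.51% without the shallow library) and 4.87% in non-invasive Kyse30 libraries, against 0.987% to 1.17% in the other groups of the line. A fit of the invasive and non-invasive groups alone called 0 genes, with 488 at an unadjusted p under 0.05, while over all groups DESeq2 called 93 higher and 323 lower and limma-voom 128 higher and 116 lower.

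**Figure D3:**
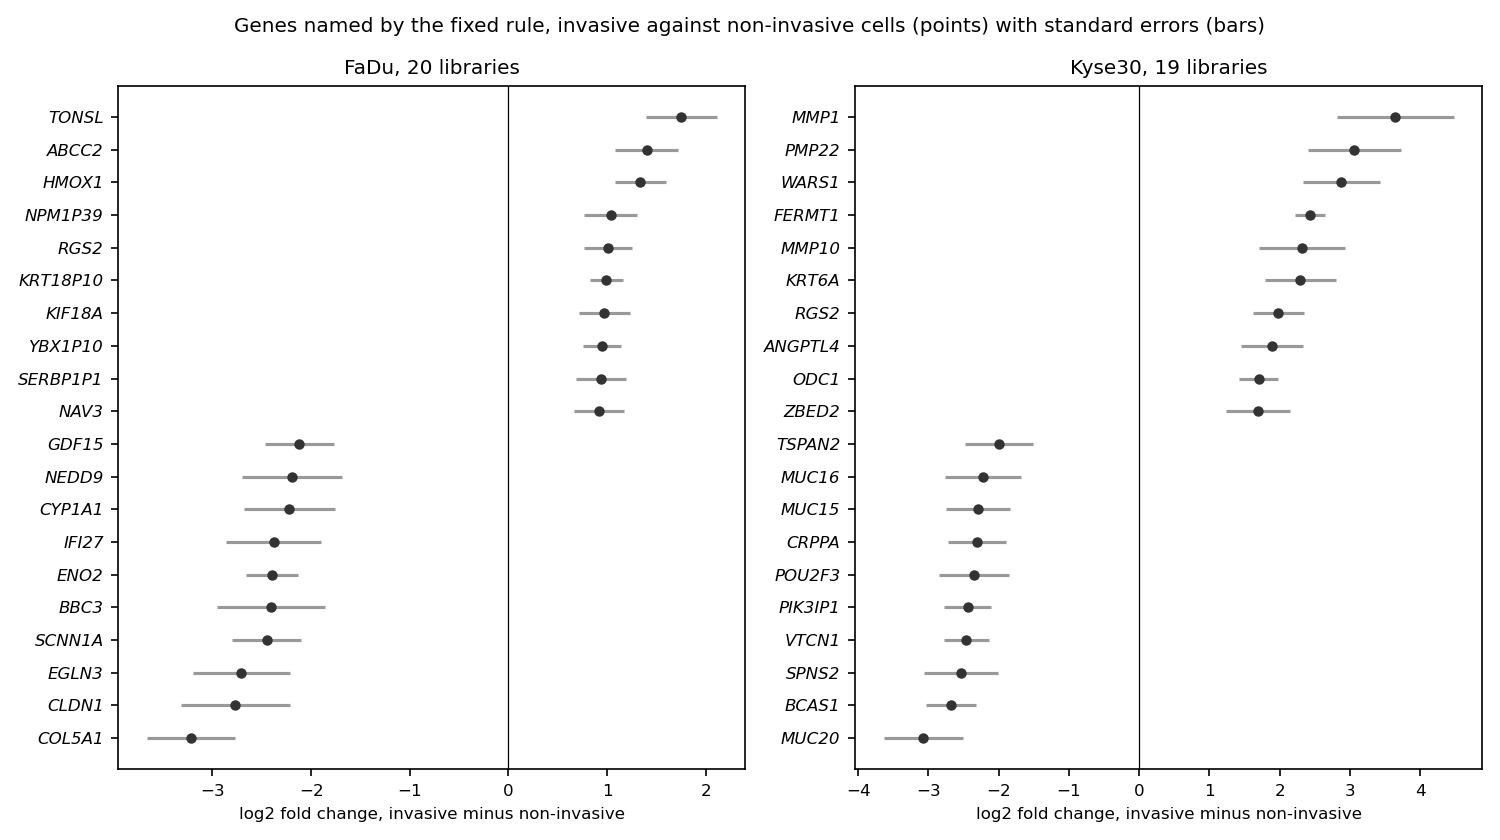
Log2 fold changes of invasive against non-invasive cells for the 10 highest and 10 lowest genes named by the fixed rule, with a point per gene and a bar for 1 SE, for FaDu and for Kyse30 without the shallow library. COL5A1 in FaDu lay at -3.22 and FERMT1 in Kyse30 at 2.44.

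FERMT1 rose and LCN2, SOX4 and CTSD fell with invasion in both lines, 4 genes where independent lists would share 0.0552 higher and 0.823 lower (one-sided Fisher's exact test for the genes higher in both, p = 0.054). FERMT1 was higher by 0.57 ± 0.13 in FaDu and 2.20 ± 0.28 in Kyse30. LCN2 was lower by -3.30 ± 0.70 and -3.57 ± 0.80, the transcription factor SOX4 by -0.65 ± 0.13 and -1.05 ± 0.24, and the lysosomal protease cathepsin D, from CTSD, by -0.49 ± 0.12 and -0.96 ± 0.20. LCN2 was no longer called in Kyse30 without the shallow library, at an adjusted p of 0.11 from edgeR's quasi-likelihood test. The 4 shared genes became 2 with the stricter filter, 1 with replicate numbers as a block and 1 without replicate 2. By edgeR they became 0 without replicate 3 and 0 without replicate 4, where 149 and 161 genes had an unadjusted p under 0.05 and the same direction in both lines, while DESeq2 and limma-voom with all libraries gave 53 and 37. Without the shallow library alone the Kyse30 fit shared 7 higher and 16 lower genes with FaDu, where 0.581 and 3.39 were expected (p = 1.7e-06 by the same Fisher's exact test on the higher genes).

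Higher in invasive cells than in each of the other 4 groups were 51 genes in FaDu and 7 in Kyse30, 66 without the shallow library. Without replicates 1, 2, 3 and 4 of every group in turn these counts were 27, 26, 4 and 3 in FaDu and 53, 1, 1 and 0 in Kyse30, the last from edgeR with 170 genes at an unadjusted p under 0.05. DESeq2 and limma-voom with all libraries gave 115 and 232 in FaDu and 58 and 110 in Kyse30. In FaDu the 51 genes included HMOX1, TONSL, RGS2, NAV3, the phospholipase gene PLCB4 and SERPINE2, an inhibitor of plasminogen activators and thrombin. Their smallest log2 fold changes over the 4 comparisons were 1.34, 1.13, 1.01, 0.91, 1.03 and 0.95. In Kyse30 the 7 genes included FERMT1, ODC1, IL1RL1, PYGB and DCBLD2, with smallest log2 fold changes of 2.20, 1.48, 1.44, 1.25 and 1.08. PYGB encodes a glycogen phosphorylase and DCBLD2 a membrane receptor.

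Treatment with EGF was read from the non-invasive cells against serum-free spheroids, a comparison in which sorting by position and treatment changed together. In FaDu the collagenase MMP1 was higher by 8.80 ± 0.89 log2 units (SE), the calcium-binding protein calretinin, from CALB2, by 8.65 ± 0.39 and IL1RL1 by 8.63 ± 0.86. IGFN1, the endothelial proteoglycan gene ESM1 and the hyaluronan synthase HAS3 had 0 counts in serum-free FaDu and were at least 153-fold, 60.8-fold and 55.6-fold higher. The keratins KRT4 and KRT13 of stratified mucosa fell by -9.14 ± 0.64 and -7.40 ± 0.66 and ceruloplasmin, from CP, by -7.67 ± 0.54. ATP6V1B1, a proton pump subunit, went to 0 counts, at least 314-fold lower. EGFR fell by -1.36 ± 0.13 and its partners ERBB2 and ERBB3 by -1.26 ± 0.13 and -2.37 ± 0.22, while the ligand TGFA rose by 2.77 ± 0.21.

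Of 12131 genes, 3071 were higher and 2997 lower in non-invasive EGF-treated than in serum-free FaDu cells. All 20 DNA replication genes and 19 of 20 G2/M genes rose, 20 and 20 adjusted over the list alone, with CDC6 at 4.31 ± 0.24 and BIRC5 at 4.40 ± 0.24 (replication, camera adjusted p = 7.2e-12, adjusted p = 0.042 with an estimated correlation). For the G2/M genes the test gave camera adjusted p = 1.4e-17, adjusted p = 0.041 with an estimated correlation. Of the ERK output genes 16 of 21 rose and 1 fell, 16 and 1 adjusted over the list alone, with the transcription factors ETV4 and ETV5 at 5.80 ± 0.46 and 3.87 ± 0.36 (camera adjusted p = 2.2e-06, adjusted p = 0.051 with an estimated correlation). Of the partial EMT markers 19 of 27 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 7.1e-07, adjusted p = 0.042 with an estimated correlation). Of the laminin-332 and integrin genes 13 of 16 rose and 2 fell, as many adjusted over the list alone, ITGA2 by 3.64 ± 0.23 (camera adjusted p = 2.2e-06, adjusted p = 0.042 with an estimated correlation). Of the actin and motility genes 20 of 25 rose and 2 fell, as many adjusted over the list alone, among them the bundling protein gene FSCN1 at 3.17 ± 0.14 (camera adjusted p = 2.1e-08, adjusted p = 0.041 with an estimated correlation). Of the squamous differentiation genes 1 rose and 7 of 10 fell, as many adjusted over the list alone (camera adjusted p = 0.0061, adjusted p = 0.042 with an estimated correlation). Of the cholesterol synthesis genes 17 of 20 rose, 19 adjusted over the list alone, with SQLE at 1.92 ± 0.18 (camera adjusted p = 3.4e-07, adjusted p = 0.21 with an estimated correlation).

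In Kyse30 the same comparison was led by IL1RL1, higher by 9.65 ± 0.60, by the activin subunit INHBA at 8.54 ± 1.14 and by IFIT1, an interferon-induced inhibitor of viral RNA translation, at 8.99 ± 1.50. XAF1, IFI44L and the chemokine CCL5 had 0 counts in serum-free Kyse30 and were at least 86.0-fold, 70.8-fold and 47.1-fold higher. The ephrin receptor EPHA7 fell by -8.55 ± 0.63, KRT4 by -6.86 ± 0.48, the cadherin FAT3 by -5.46 ± 0.43 and CYP1A1, the aryl hydrocarbon receptor's best-known target, by -5.91 ± 0.41. ATP12A, a proton-potassium pump, went to 0 counts, at least 95.2-fold lower.

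Of 11976 genes 970 were higher and 570 lower, and without the shallow invasive library 1917 and 1443. In the full fit 14 of 20 interferon response genes rose, 17 adjusted over the list alone, with a median of 3.41 (camera adjusted p = 4.7e-09, adjusted p = 0.22 with an estimated correlation). Of the NF-kB cytokines and chemokines 6 of 9 rose, 7 adjusted over the list alone (camera adjusted p = 2.9e-06, adjusted p = 0.14 with an estimated correlation). Of the laminin-332 and integrin genes 11 of 16 rose, 12 adjusted over the list alone (camera adjusted p = 2.0e-09, adjusted p = 0.14 with an estimated correlation). Partial EMT markers had 15 of 27 higher and 1 lower, 19 and 1 adjusted over the list alone, with vimentin, from VIM, at 6.61 ± 0.68 and TGFBI at -2.19 ± 0.23 (camera adjusted p = 3.4e-10, adjusted p = 0.14 with an estimated correlation). Without the shallow library both of these lists passed with an estimated correlation, at adjusted p = 0.048 and 0.048. The hypoxia list had 9 of 18 higher, 11 adjusted over the list alone, EGLN3 by 4.87 ± 0.68 (camera adjusted p = 5.5e-06, adjusted p = 0.37 with an estimated correlation). Of the ERK output genes 4 of 21 rose and 3 fell, 7 and 4 adjusted over the list alone, and ETV4 and the feedback inhibitor SPRY1 fell by -1.30 ± 0.23 and -3.23 ± 0.33 without the shallow library. With DESeq2 size factors 51.8% of the calls were higher, against 63.0% with TMM.

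Invasive cells were also compared with serum-free spheroids. In FaDu MMP1 was higher by 9.66 ± 0.87, the channel gene TRPV3 by 9.10 ± 0.96, and CP and KRT4 were lower by -10.64 ± 0.72 and -10.63 ± 0.75. The cytokine gene IL24 and ESM1, with 0 counts in serum-free FaDu, were at least 71.0-fold and 107-fold higher. In Kyse30 IL1RL1 and INHBA were higher by 11.09 ± 0.59 and 9.79 ± 1.13, and EPHA7 went to 0 counts, at least 191-fold lower. Calls were 3371 higher and 3579 lower in FaDu and 1438 and 1748 in Kyse30, 2367 and 2283 without its shallow library. The hypoxia list had 1 of 18 higher and 9 lower in FaDu, as many adjusted over the list alone (camera adjusted p = 0.047, adjusted p = 0.62 with an estimated correlation). In Kyse30 11 of 18 rose, 12 adjusted over the list alone (camera adjusted p = 5.4e-05, adjusted p = 0.44 with an estimated correlation). The G2/M list rose in 20 of 20 members in FaDu, as many adjusted over the list alone (camera adjusted p = 1.5e-16, adjusted p = 0.052 with an estimated correlation).

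Cetuximab was compared with the non-invasive EGF-treated cells, which were sorted by position while the cetuximab spheroids were unselected. In FaDu the mucosal keratins KRT13 and KRT4 were higher by 4.25 ± 0.69 and 3.92 ± 0.76, the insulin-like gene IGFL1 by 4.09 ± 0.52 and the aldehyde dehydrogenase ALDH3A1 by 3.31 ± 0.36. The plasminogen activator inhibitor SERPINB2 was lower by -7.34 ± 0.79, the transcriptional repressor PRDM1 by -6.37 ± 0.77, INHBA by -5.44 ± 0.62 and MMP1 by -4.10 ± 0.54. ESM1 had 0 counts with cetuximab, at least 78.9-fold lower. DUSP6 fell by -2.03 ± 0.27 and the feedback inhibitor SPRY2 by -3.15 ± 0.42.

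In FaDu 441 genes were higher and 598 lower with cetuximab. Of the partial EMT markers 13 of 27 fell and 1 rose, 17 and 2 adjusted over the list alone (camera adjusted p = 2.0e-11, adjusted p = 0.008 with an estimated correlation). Of the actin and motility genes 11 of 25 fell, 16 adjusted over the list alone, with MYH9 at -0.73 ± 0.11 and ZYX at -0.97 ± 0.15 (camera adjusted p = 1.6e-12, adjusted p = 0.008 with an estimated correlation). Of the laminin-332 and integrin genes 7 of 16 fell, 9 adjusted over the list alone (camera adjusted p = 3.3e-09, adjusted p = 0.021 with an estimated correlation). Of the NF-kB cytokines 8 of 14 fell, 8 lower and 1 higher adjusted over the list alone, with CXCL8 at -2.60 ± 0.26 and the prostaglandin synthase PTGS2 at -4.28 ± 0.61 (camera adjusted p = 6.0e-10, adjusted p = 0.065 with an estimated correlation). Of the interferon genes 8 of 22 fell, 14 adjusted over the list alone (camera adjusted p = 8.8e-09, adjusted p = 0.097 with an estimated correlation). Among ERK output genes 3 of 21 fell, 5 adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.17 with an estimated correlation). Of the matrix proteases and inhibitors 6 of 16 fell, 9 adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.065 with an estimated correlation). Of the ribosomal proteins 8 of 30 rose, 21 adjusted over the list alone, RPLP0 by 0.61 ± 0.10 (camera adjusted p = 3.3e-09, adjusted p = 0.12 with an estimated correlation). The count fell to 609 without cetuximab replicate 3.

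In Kyse30 cetuximab went with higher EPHA7, by 7.51 ± 0.63, FAT3 by 4.86 ± 0.43, the kinase CAMK4 by 4.96 ± 0.59, KRT4 by 4.62 ± 0.45 and the collagen COL12A1 by 4.61 ± 0.67. Lower were the interferon-induced OASL by -4.97 ± 0.85, KRT6A by -4.71 ± 0.67, INHBA by -4.31 ± 0.73 and the cytokine IL32 by -4.24 ± 0.70. LAMB3 fell by -2.13 ± 0.25. Calls were 221 higher and 369 lower, and 890 and 1178 without the shallow library of another group. With DESeq2 size factors 50.3% of the calls were higher, against 37.5%. Of the hypoxia genes 8 of 18 fell, 10 adjusted over the list alone, with ERO1A at -1.39 ± 0.23 (camera adjusted p = 1.0e-07, adjusted p = 0.26 with an estimated correlation). Of the interferon genes 8 of 20 fell, 16 adjusted over the list alone, with a median of -2.71 (camera adjusted p = 1.8e-08, adjusted p = 0.26 with an estimated correlation). Of the partial EMT markers 12 of 27 fell, 14 adjusted over the list alone and 1 higher (camera adjusted p = 3.1e-10, adjusted p = 0.18 with an estimated correlation). Of the AP-1 and immediate early genes 4 of 12 fell, 6 adjusted over the list alone, KLF6 by -1.52 ± 0.24 (camera adjusted p = 2.9e-04, adjusted p = 0.26 with an estimated correlation). Of the cholesterol synthesis genes 5 of 20 fell, 10 adjusted over the list alone (camera adjusted p = 3.1e-06, adjusted p = 0.31 with an estimated correlation). The YAP/TEAD targets had 4 of 14 lower, as many adjusted over the list alone, with the ecto-nucleotidase gene NT5E at -1.46 ± 0.24 (camera adjusted p = 0.0061, adjusted p = 0.4 with an estimated correlation).

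With the MEK inhibitor, in unselected spheroids set against the sorted non-invasive cells, FaDu had higher CP by 7.52 ± 0.54, KRT4 by 6.90 ± 0.65, IGFL1 by 6.50 ± 0.51, the endothelin EDN2 by 6.91 ± 0.81 and the complement protease C1R by 5.74 ± 0.63. MMP1 fell by -9.72 ± 0.94, IL1RL1 by -9.69 ± 0.92 and SERPINB2 by -7.96 ± 0.85. IGFN1 and ESM1 went to 0 counts, at least 179.9-fold and 71.5-fold lower. DUSP6, PHLDA1 and ETV4 fell by -5.42 ± 0.33, -4.28 ± 0.23 and -4.49 ± 0.38, and EGFR rose by 0.85 ± 0.13.

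In FaDu 1796 genes were higher and 1806 lower with the MEK inhibitor. Of the ERK output genes 18 of 21 fell, as many adjusted over the list alone, with a median of -2.44 (camera adjusted p = 3.4e-12, adjusted p = 0.016 with an estimated correlation). Of the laminin-332 and integrin genes 12 of 16 fell and 1 rose, 13 and 2 adjusted over the list alone (camera adjusted p = 2.0e-09, adjusted p = 0.016 with an estimated correlation). Of the DNA replication genes 12 of 20 fell, 14 adjusted over the list alone, CDC6 by -1.42 ± 0.19 (camera adjusted p = 6.5e-05, adjusted p = 0.29 with an estimated correlation). Of the interferon genes 11 of 22 rose, 15 adjusted over the list alone, IFIT1 by 3.02 ± 0.43 and IFI44L by 3.73 ± 0.62 (camera adjusted p = 5.0e-05, adjusted p = 0.29 with an estimated correlation). Of the stress keratins and alarmins 5 of 6 rose and 1 fell, as many adjusted over the list alone, with the protease inhibitor SLPI at 3.26 ± 0.26, S100A9 at 3.82 ± 0.56 and KRT6A at -4.63 ± 0.47 (camera adjusted p = 0.0065, adjusted p = 0.036 with an estimated correlation). Of the ribosomal proteins 14 of 30 fell, as many adjusted over the list alone (camera adjusted p = 5.9e-04, adjusted p = 0.46 with an estimated correlation). The basal keratinocyte list had 4 of 12 higher and 5 lower, 4 and 7 adjusted over the list alone, with KRT5 at 3.76 ± 0.36 and ITGB4 at -1.81 ± 0.16 (camera adjusted p = 0.44, adjusted p = 0.6 with an estimated correlation).

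In Kyse30 the MEK inhibitor went with EPHA7 higher by 7.58 ± 0.63, COL12A1 by 5.47 ± 0.67 and the guidance gene SEMA5A by 5.10 ± 0.68, while the matrix protease gene ADAMTS5 rose from 0 counts by at least 55.2-fold. IL1RL1 fell by -8.00 ± 0.49, VIM by -5.20 ± 0.57 and S100A2 by -4.40 ± 0.67. Calls were 198 higher and 348 lower, 705 and 1033 without the shallow library. With DESeq2 size factors 49.2% of the calls were higher, against 36.3%. Of the ERK output genes 8 of 21 fell and 1 rose, 9 and 2 adjusted over the list alone, PHLDA1 by -1.40 ± 0.25 (camera adjusted p = 7.7e-07, adjusted p = 0.16 with an estimated correlation). Of the laminin-332 and integrin genes 9 of 16 fell, 11 adjusted over the list alone, ITGB4 by -2.11 ± 0.29 (camera adjusted p = 4.8e-13, adjusted p = 0.12 with an estimated correlation, and 0.023 without the shallow library). The EGFR family list had 2 of 11 lower, 3 adjusted over the list alone, with the ligand HBEGF at -3.29 ± 0.37 and the feedback inhibitor ERRFI1 at -1.89 ± 0.41 (camera adjusted p = 0.015, adjusted p = 0.28 with an estimated correlation). Of the DNA replication genes 3 of 20 rose, 3 adjusted over the list alone (camera adjusted p = 1.0e-04, adjusted p = 0.51 with an estimated correlation). In the fit that leaves out the shallow library 11 rose, 16 adjusted over the list alone (camera adjusted p = 3.7e-08, adjusted p = 0.087 with an estimated correlation).

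**Figure D4:**
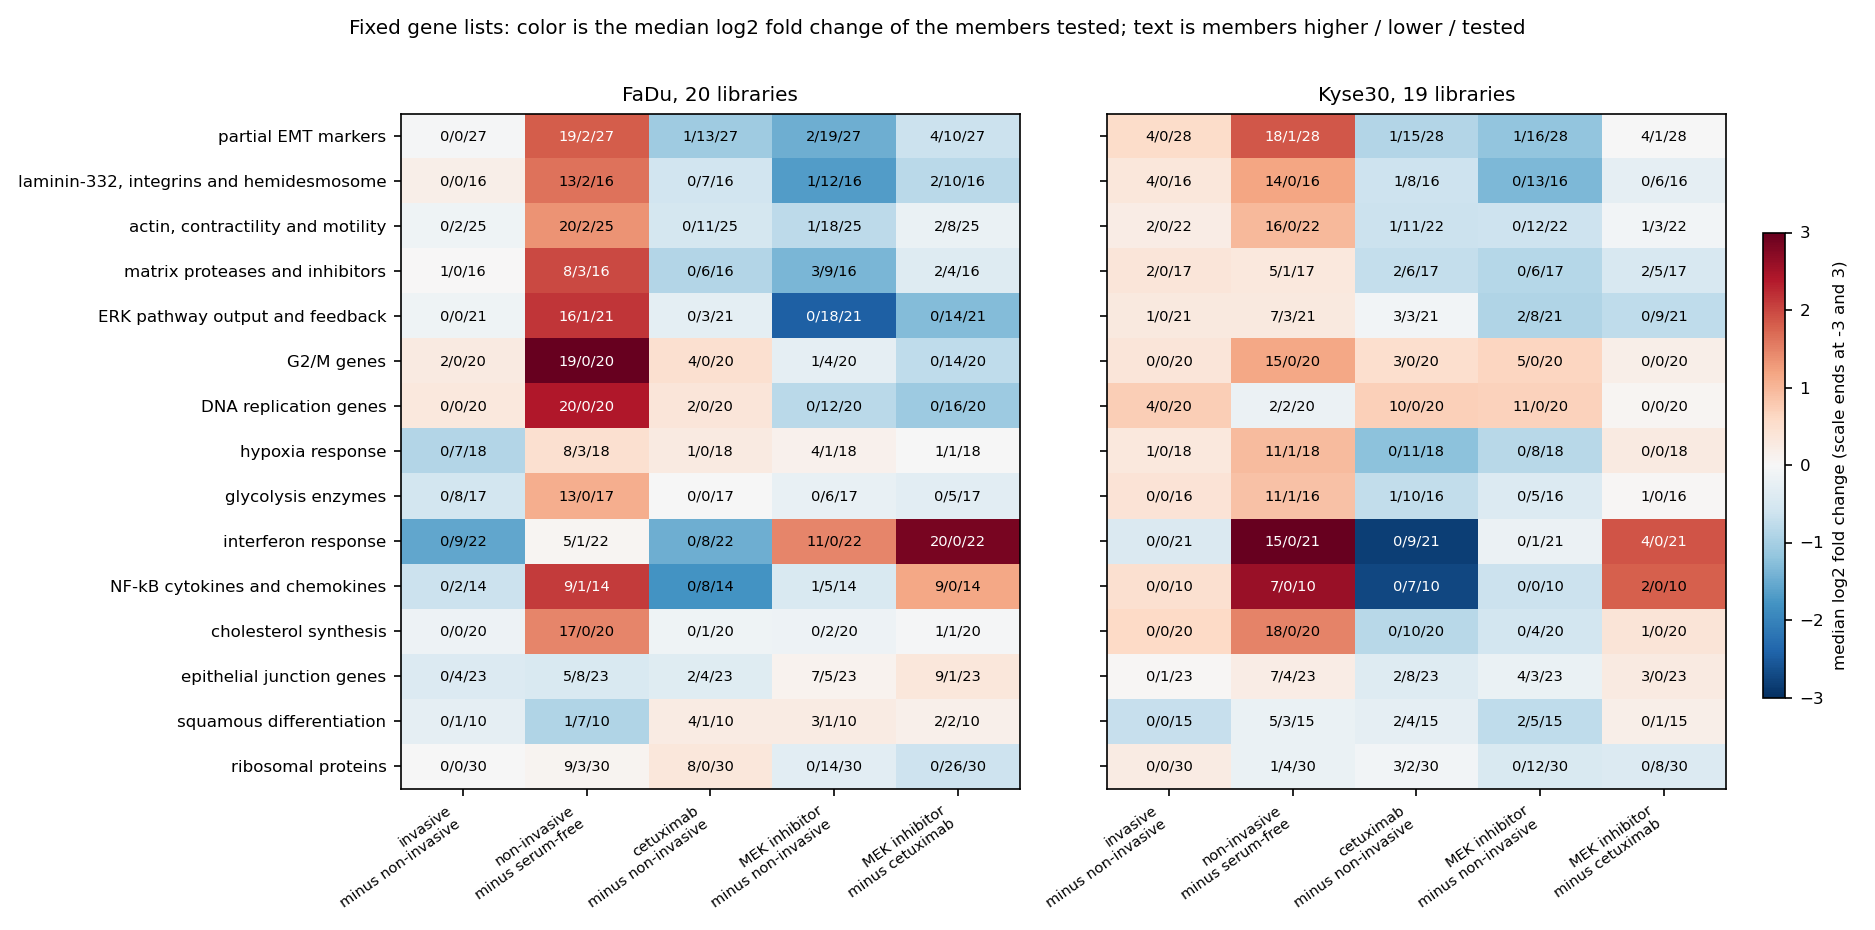
Median log2 fold change of the members of 15 of the gene lists, with a column for each of 5 comparisons for FaDu and for Kyse30 without the shallow library, a colour scale in log2 units and the numbers of members higher, lower and tested. The hypoxia list lay at -0.88 in FaDu and 0.31 in Kyse30 for invasive against non-invasive cells.

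The drugs were also set against serum-free spheroids, where all samples were unselected. In FaDu with EGF and cetuximab CALB2 stayed higher by 8.28 ± 0.39, the activin antagonist gene FST by 6.30 ± 0.67 and ETV4 by 5.94 ± 0.45, while ATP6V1B1 was lower by -7.79 ± 0.52. With EGF and the MEK inhibitor IFI27 was higher by 5.33 ± 0.57, IGFL1 by 4.79 ± 0.44 and the mitotic genes BIRC5 and CDC20 by 4.06 ± 0.23 and 3.92 ± 0.21, while ATP6V1B1 was lower by -4.74 ± 0.39. All 20 G2/M genes rose with either drug in FaDu, with medians of 3.69 for cetuximab (camera adjusted p = 8.8e-24, adjusted p = 0.011 with an estimated correlation) and 3.04 for the MEK inhibitor (camera adjusted p = 4.7e-37, adjusted p = 0.0013 with an estimated correlation). Among ERK output genes 14 of 21 were higher and 1 lower than in serum-free FaDu with cetuximab, as many adjusted over the list alone (camera adjusted p = 6.9e-05, adjusted p = 0.18 with an estimated correlation). With the MEK inhibitor 2 were higher and 3 lower, as many adjusted over the list alone, and the median and the test differed in sign. Calls in FaDu were 2754 higher and 2560 lower for cetuximab and 1308 and 1047 for the MEK inhibitor.

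In Kyse30 with EGF and cetuximab IL1RL1 was higher than without serum by 6.99 ± 0.66, the glutamate transporter SLC1A6 by 6.69 ± 0.99 and the mitotic checkpoint gene BUB1B by 3.07 ± 0.54, while the water channel AQP3 and CYP1A1 were lower by -5.14 ± 0.87 and -3.70 ± 0.36. With EGF and the MEK inhibitor XAF1, UBD and IDO1 rose from 0 counts by at least 174-fold, 88.4-fold and 66.6-fold and the antigen presentation gene CD74 by 7.13 ± 1.21, while PADI1 fell by -4.76 ± 0.54. Calls were 225 higher and 150 lower for cetuximab and 274 and 193 for the MEK inhibitor, against 1053 and 775 and 1028 and 833 without the shallow library. Of the interferon genes 11 of 20 rose with the MEK inhibitor, 18 adjusted over the list alone (camera adjusted p = 1.7e-18, adjusted p = 0.19 with an estimated correlation). Of the mitochondrially encoded mRNAs 7 of 13 fell with cetuximab and 8 with the MEK inhibitor, 10 and 11 adjusted over the list alone (camera adjusted p = 2.7e-13, adjusted p = 0.36 with an estimated correlation for cetuximab, and camera adjusted p = 3.0e-13, adjusted p = 0.19 with an estimated correlation for the MEK inhibitor).

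Set against each other within FaDu, the MEK inhibitor gave higher interferon-induced IFI44L by 5.88 ± 0.74, the complement genes CFB and C1S by 5.57 ± 0.51 and 4.16 ± 0.50 and CP by 4.69 ± 0.41 than cetuximab, and lower ETV4 by -4.62 ± 0.38, the chromatin protein HMGA2 by -4.96 ± 0.35, CALB2 by -4.59 ± 0.27 and the anchoring protein AKAP12 by -3.52 ± 0.52. Calls were 1036 higher and 1359 lower. Of the interferon genes 20 of 22 were higher, as many adjusted over the list alone (camera adjusted p = 7.1e-17, adjusted p = 0.023 with an estimated correlation). Of the ERK output genes 14 of 21 were lower, 16 adjusted over the list alone (camera adjusted p = 3.3e-12, adjusted p = 0.013 with an estimated correlation). Of the DNA replication genes 16 of 20 and of the ribosomal proteins 26 of 30 were lower, 18 and 29 adjusted over the list alone (replication, camera adjusted p = 3.4e-10, adjusted p = 0.071 with an estimated correlation). For the ribosomal proteins the estimated correlation gave an adjusted p = 0.064.

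In Kyse30 the MEK inhibitor gave higher CD74, from 0 counts with cetuximab and by at least 102-fold, the tryptophan-degrading IDO1 by 6.49 ± 1.39 and the GTPase GBP1 by 5.07 ± 0.93, and lower IL1RL1 by -5.34 ± 0.50, CALB2 by -3.32 ± 0.61 and AKAP12 by -3.19 ± 0.46. Calls were 71 higher and 70 lower, 270 and 293 without the shallow library. Of the interferon genes 3 of 20 were higher, 14 adjusted over the list alone (camera adjusted p = 3.3e-22, adjusted p = 0.079 with an estimated correlation). Among ERK output genes 5 of 21 were lower, 10 adjusted over the list alone (camera adjusted p = 3.0e-10, adjusted p = 0.079 with an estimated correlation).

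Among the genes raised by EGF in FaDu 1545 were lowered by the MEK inhibitor, and among those lowered by EGF 1507 were raised, where independent lists would give 457.19 and 443.71. For cetuximab the numbers were 469 and 275, where 151.39 and 108.95 were expected. These comparisons share the non-invasive libraries, and the covariance of their log2 fold changes was -1.12 for the MEK inhibitor and -0.45 for cetuximab, against a mean of -0.05 in simulations of unchanged groups. With the non-invasive libraries divided between the comparisons, 974 and 851 genes (254.7 and 211 expected) and a covariance of -1.13 were found for the MEK inhibitor, and 285 and 119 genes (81.26 and 41.58 expected) and -0.42 for cetuximab. In Kyse30 cetuximab lowered 259 and raised 141 and the MEK inhibitor lowered 253 and raised 132 of the genes that EGF had moved the other way, where 29.89, 10.52, 28.19 and 9.42 were expected, with covariances of -0.56 and -0.52 against -0.09 in simulations. In divided fits 98 and 52 genes (5.34 and 1.14 expected) and 123 and 50 genes (8.15 and 1.43 expected) were found, with covariances of -0.54 and -0.47. The drugs shared 271 higher and 463 lower genes against non-invasive FaDu cells (65.29 and 89.03 expected) and 105 and 168 in Kyse30 (3.65 and 10.72 expected), with covariances of 0.40 and 0.44 against 0.05 and 0.09 in simulations. With the libraries divided these were 88 and 247 genes in FaDu (13.15 and 31.44 expected) and 31 and 52 in Kyse30 (0.62 and 3.46 expected), with covariances of 0.38 and 0.34. In the 10 simulations of unchanged groups at most 1 gene was called per comparison. The expected numbers leave out the shared libraries and the simulations leave out the effects. The non-invasive cells were sorted by position, while the serum-free and drug spheroids were unselected. An effect of sorting would enter the EGF and drug comparisons with opposite signs, and the drug comparisons with the same sign. Neither the simulations nor the divided fits remove it, so these overlaps cannot tell sorting from treatment.

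The lines were compared by testing the Kyse30 effect minus the FaDu effect. For invasive against non-invasive cells 23 genes differed, 18 with a higher and 5 with a lower effect in Kyse30, and 74 without the shallow library. Without replicate 2, 3 or 4 of every group edgeR called 1, 0 and 0, the 0 counts beside 727 and 995 genes at an unadjusted p under 0.05, and the 9 genes taken by the naming rule lost their calls each time. DESeq2 and limma-voom with all libraries called 145 and 131. ENO2 differed by 2.84 ± 0.65 log2 units, the creatine transporter SLC6A8 by 2.97 ± 0.64 and the ion cotransporter SLC12A2 by -1.44 ± 0.30. Without the shallow library the hypoxia list had a median difference of 1.46, with 7 of 18 members called, and passed camera with an estimated correlation at adjusted p = 0.016, and glycolysis followed with 0.96, 6 of 17 and 0.014. The partial EMT markers, with 0.74 and 0 of 29 called, and the actin and motility list, with 0.43 and 2 of 25, passed as well at 0.017 and 0.044. With all 40 libraries these adjusted p were 0.23, 0.10, 0.23 and 0.14 with an estimated correlation. For non-invasive cells against serum-free spheroids 1983 genes differed, 1199 with a higher and 784 with a lower effect in Kyse30. Without the shallow library the DNA replication list differed by a median of -2.90, with 19 of 20 members called, the G2/M list by -2.01, with 17 of 20, and the ERK list by -1.57 (adjusted p = 0.0068, 0.027 and 0.021 with an estimated correlation, and 0.25, 0.45 and 0.098 over 40 libraries). For cetuximab 166 genes differed and for the MEK inhibitor 645. Over the alternatives these counts ran from 25 to 1002 and from 147 to 2135, and the count of 1983 from 827 to 3561. Over 39 libraries the MEK inhibitor's effect on the ERK list differed by 1.26 and on the replication list by 1.61 (adjusted p = 0.032 and 0.031 with an estimated correlation, and 0.13 and 0.50 over 40).

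The remaining lists are given for 1 comparison each. Of the EMT transcription factors and mesenchymal genes 2 of 9 rose and 3 fell in non-invasive against serum-free FaDu, as many adjusted over the list alone, TWIST2 by 1.85 ± 0.26 and S100A4 by -3.10 ± 0.29 (camera adjusted p = 0.78, adjusted p = 0.82 with an estimated correlation). Of the TGF-beta response genes 7 of 15 rose and 5 fell, as many adjusted over the list alone, ID1 by -1.55 ± 0.20 (camera adjusted p = 0.56, adjusted p = 0.82 with an estimated correlation). Of the integrated stress and unfolded protein response genes 8 of 20 rose, as many adjusted over the list alone (camera adjusted p = 0.14, adjusted p = 0.6 with an estimated correlation). Of the markers of other cell types 1 fibroblast, 1 leukocyte and 1 endothelial gene were tested, too few for a set test, and 0 erythrocyte genes were in the table. The fibroblast gene COL1A1 was lower in non-invasive than in serum-free FaDu by -1.38 ± 0.36, the leukocyte gene CD68 higher by 3.00 ± 0.60 and the endothelial cadherin CDH5 lower by -5.29 ± 1.19, from 3.41 CPM.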

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

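The hypoxia, detection, parent gene and genomic DNA tests in this part were chosen only after the results they concern were seen, as were the 5 oxidative stress genes themselves.

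A library was singled out where it stood apart from the other 3 of its group by more than a critical gap, which chance does in about 1 in 20 groups, and 6 of 100 values tested did so. The first invasive Kyse30 library had 5281 genes detected, where the other 3 had 12004 to 12254, and 26.6% of its counts in mitochondrial genes, where they had 11.7% to 13.05%. In FaDu the fourth cetuximab library had 1.23% of its counts in MALAT1 (others 0.806% to 0.878%), and the first MEK inhibitor library 11952 genes detected (12384 to 12407). The first MEK inhibitor library of Kyse30 had a total of 4072449 counts (3339892 to 3457243).

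Effects that differed between the cell lines, by an interaction test of the Kyse30 effect minus the FaDu effect, numbered 23 genes for invasive against non-invasive cells, 1983 for non-invasive cells against serum-free spheroids, 166 for cetuximab and 645 for the MEK inhibitor. Over the alternatives these counts ran from 0 to 145, 827 to 3561, 25 to 1002 and 147 to 2135. With invasion the difference was 2.97 log2 units for SLC6A8, 2.84 for ENO2, 2.82 for WARS1, -3.63 for SYCP2L, -3.002 for ANTXR2, -2.62 for DYNC2H1 and -1.44 for SLC12A2. With EGF it was -7.09 for ETV4. With cetuximab it was 6.37 for PCDH9, 5.80 for COL12A1, 5.23 for ZNF703, -5.50 for IGFL1 and -4.89 for CP, and with the MEK inhibitor 7.25 for COL12A1, 5.975 for PTGS2, -7.33 for IGFL1 and -7.23 for CP. Genes with a group at or under 3 counts were left out here, a choice made after their values were seen, which removed 2, 9, 5 and 6 of the genes named for the 4 comparisons. Of the genes given, ZNF703 in FaDu and IGFL1 in Kyse30 did not pass the expression filter of that line's own fit. Their differences therefore rest on low counts in that line.

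Other divisions of the same samples into groups of the same sizes were counted for each result. In FaDu 1 of 35 splits, the real one, reached its count in all 8 comparisons. At that level a random division of these samples is an unlikely source. Chance between cultures was not tested, since the replicates may be technical. The real counts and the highest of the others were 364 and 0 for invasive against non-invasive cells, 6068 and 0 for non-invasive against serum-free, 6950 and 0 for invasive against serum-free, 1039 and 94 for cetuximab and 3602 and 1 for the MEK inhibitor against non-invasive, 5314 and 1 and 2355 and 33 for the drugs against serum-free, and 2395 and 252 for the MEK inhibitor against cetuximab. In Kyse30 it was also 1 of 35 in each, with 1540 and 0, 3186 and 895, 590 and 0, 546 and 0, 375 and 0, 467 and 0, and 141 and 3 in the same order after the first comparison. For invasive against non-invasive Kyse30 cells the real count was 49 and the highest other 47, and without the shallow library 253 and 251. These others put non-invasive replicate 4 with invasive replicates 2, 3 and 4, apart from non-invasive replicates 1, 2 and 3. In the full set the shallow invasive replicate 1 stood with the latter. Such splits keep most of the real division, so they cannot tell sorting from another structure among these samples. For genes higher in invasive cells than in each other group 1 of 70 splits reached the count in FaDu (51, highest other 11) and 3 of 70 in Kyse30 (7, highest other 15). For differences between the lines 4 of 100 splits reached 23 (highest other 63), 1 of 100 reached 1983 (1827), 2 of 100 reached 166 (536) and 1 of 100 reached 645 (606). The lines were divided independently, so a split could keep or reverse the real division in 1 line and mix the other. An effect shared by the lines would then count as a difference. These splits therefore do not show what equal effects would give. Why other splits called as many as 63 and 536 genes was not tested. For genes called in both lines with invasion 1 of 100 splits reached 4 (highest other 1). The other FaDu splits called 0 genes, so pairs that used them could not share any. That outcome was largely fixed in advance and adds no evidence against chance for the 4 genes. All of these shares are under 0.05, the bound set for excluding chance. With 35 splits that bound asks only that no other split reach the real count. Meeting it is weak evidence for 49 against 47 and 253 against 251. The same holds for the differences between the lines with 1983 against 1827 and 645 against 606. It is weak too where other splits passed the real counts, with 15 against 7, 63 against 23 and 536 against 166.

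Lower hypoxia and glycolysis genes in invasive FaDu cells were weighed first, with 15 of 35 members called lower and 0 higher. Fewer genes were detected in the invasive libraries. Yet the 25 members in the upper part of mean expression had a median of -0.66 (bootstrap 95% interval over genes -0.96 to -0.42). Of these members 13 were called, which argues against a loss of weakly detected genes. All bootstrap intervals in this part were drawn over genes and not over libraries. They leave out the spread between libraries and treat related genes as independent. At least 11 of the 15 were still called with any 1 of the 8 libraries left out, which argues against a single library. A candidate explanation is that cells in the spheroid's interior have less oxygen than cells that moved into the collagen, which was not tested, as the design holds no oxygen measurement. In Kyse30 without the shallow library 0 of 34 members were lower and 1 was higher, with a median of 0.36.

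Oxidative stress genes were weighed next, since HMOX1, ABCC2, SLC7A11, GCLM and TXNRD1 were all called higher in invasive FaDu cells, with a median of 0.90. Light of the photoconversion may be a source if it reached invasive cells alone. The protocol names invasive areas as photoconverted, but the titles call the non-invasive cells photoconverted too, so it is unclear whether the groups differ in light at all. Kyse30 without the shallow library had a median of 0.39 and 1 of the 5 called. The median difference between the lines was -0.51 (-1.47 to 0.0074), too wide to decide, so light stays open. Further targets of the transcription factor NRF2 were written down before their values were seen, and 15 of them, all but AKR1B10, were tested. They had a median of 0.30 (0.15 to 0.54), with 1 of them, NQO1, called, and camera with an estimated correlation gave p = 0.024. A wider response of that factor thus stays possible, with an interval that leaves out the spread between libraries.

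Pseudogenes made up 6 of the 80 genes higher in invasive FaDu cells, where 3.82 would be expected (Fisher's exact test, p = 0.282). Reads of the parent genes may have been counted at them. Parents were matched by symbol. The 4 distinct parents found had a median of 0.43 (0.096 to 0.74), 2 of them called, beside 0.95 for the 5 pseudogenes matched. The interval spans the bound set for the test, so this stays open. The match left out HSP90AB3P, so its candidate parent HSP90AB1 was not weighed. Both were higher in invasive FaDu cells than in each other group, by at least 0.54 and 0.50 log2 units. Genomic DNA is possible as well, since all 580 pseudogenes tested had a median of 0.099 (0.051 to 0.158), which spans its bound too.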

How the results depend on the processing

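The fit without 6 doubted libraries was chosen after seeing the data, and the other alternatives were planned. Of the alternative counts of calls, 218 stayed within 1.5 times the count reported and 145 did not, and of 5760 alternative list counts 5258 did. Of 27176 alternative values for named genes 26 turned their sign and 1662 lost their call. Below, invasion stands for invasive against non-invasive cells, EGF for non-invasive cells against serum-free spheroids, and each drug alone for its comparison with non-invasive cells. The cause was not tested for any of the shifts, apart from the smaller number of samples where libraries were left out. Depth was not varied by itself. On data simulated at the depths of these libraries the test of invasive against non-invasive cells recovered 17.5% of genes changed 2-fold in Kyse30 with the shallow library and 31.3% without it, and 77.8% and 73.7% of genes changed 4-fold. In FaDu it recovered 56.6% and 85.9%. The spread between libraries was estimated anew for each set of libraries, so these shares do not isolate depth.

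In FaDu, DESeq2 gave 625 for invasion and 115 for genes higher in invasive cells than in each group. Limma-voom with sample quality weights gave 784 for invasion, 2591 for cetuximab, 4184 for the MEK inhibitor against serum-free and 232 for genes higher in invasive cells than in each group. Leaving out 6 doubted libraries gave 704 for invasion, 2141 for cetuximab and 171 for genes higher in invasive cells than in each group. A single fit over all 40 libraries gave 84 for invasion, 377 for cetuximab, 1993 for the MEK inhibitor, 1058 for the MEK inhibitor against serum-free and 1010 for the MEK inhibitor against cetuximab. A fit of the compared groups alone gave 1230 for the MEK inhibitor against cetuximab. With a replicate left out in turn the counts were 209 to 331 for invasion, 609 to 1344 for cetuximab and 3 to 27 for genes higher in invasive cells than in each group. Libraries whose absence moved a count by over 1.5 times gave, for invasion 218, 237 and 209 without non-invasive replicates 1, 2 and 4. For cetuximab they gave 609 without cetuximab replicate 3. For genes higher in invasive cells than in each group they gave 27, 26, 4 and 3 without replicates 1, 2, 3 and 4.

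In Kyse30, DESeq2 gave 416 for invasion, 2430 for EGF, 1356 for cetuximab, 1135 for the MEK inhibitor, 1097 for cetuximab against serum-free, 1116 for the MEK inhibitor against serum-free, 313 for the MEK inhibitor against cetuximab and 58 for genes higher in invasive cells than in each group. Limma-voom with sample quality weights gave 244 for invasion, 3128 for EGF, 2519 for cetuximab, 2445 for the MEK inhibitor, 1569 for cetuximab against serum-free, 1986 for the MEK inhibitor against serum-free, 1350 for the MEK inhibitor against cetuximab and 110 for genes higher in invasive cells than in each group. Leaving out 6 doubted libraries gave 76 for invasion, 2867 for EGF, 4875 for invasive against serum-free, 1182 for cetuximab, 1188 for the MEK inhibitor, 2126 for cetuximab against serum-free, 2134 for the MEK inhibitor against serum-free, 725 for the MEK inhibitor against cetuximab and 14 for genes higher in invasive cells than in each group. A single fit over all 40 libraries gave 305 for invasion, 2677 for EGF, 1405 for cetuximab, 1183 for the MEK inhibitor, 1252 for cetuximab against serum-free, 1220 for the MEK inhibitor against serum-free and 307 for the MEK inhibitor against cetuximab. A fit of the compared groups alone gave 0 for invasion, 2403 for EGF, 902 for invasive against serum-free, 1484 for cetuximab, 1775 for the MEK inhibitor, 1246 for cetuximab against serum-free, 1979 for the MEK inhibitor against serum-free and 603 for the MEK inhibitor against cetuximab. Leaving out the shallow library gave 253 for invasion, 3360 for EGF, 2068 for cetuximab, 1738 for the MEK inhibitor, 1828 for cetuximab against serum-free, 1861 for the MEK inhibitor against serum-free, 563 for the MEK inhibitor against cetuximab and 66 for genes higher in invasive cells than in each group. The replicate block gave 24 for invasion. With a replicate left out in turn the counts were 7 to 253 for invasion, 316 to 497 for cetuximab, 284 to 466 for the MEK inhibitor, 176 to 310 for cetuximab against serum-free, 190 to 381 for the MEK inhibitor against serum-free, 41 to 99 for the MEK inhibitor against cetuximab and 0 to 53 for genes higher in invasive cells than in each group. Libraries whose absence moved a count by over 1.5 times gave, for invasion 22, 29 and 24 without non-invasive replicates 1, 2 and 3 and 253, 7 and 19 without invasive replicates 1, 3 and 4. For cetuximab they gave 316, 317 and 356 without cetuximab replicates 1, 3 and 4 and 347 without non-invasive replicate 1. For the MEK inhibitor they gave 359 without non-invasive replicate 4 and 363, 355, 284 and 314 without MEK inhibitor replicates 1, 2, 3 and 4. For cetuximab against serum-free they gave 201, 222, 235 and 223 without cetuximab replicates 1, 2, 3 and 4 and 176 and 181 without serum-free replicates 2 and 3. For the MEK inhibitor against serum-free they gave 245, 190, 228 and 279 without MEK inhibitor replicates 1, 2, 3 and 4 and 241, 255 and 265 without serum-free replicates 2, 3 and 4. For the MEK inhibitor against cetuximab they gave 79, 73 and 49 without cetuximab replicates 1, 3 and 4 and 60, 75 and 41 without MEK inhibitor replicates 1, 2 and 3. For genes higher in invasive cells than in each group they gave 53, 1, 1 and 0 without replicates 1, 2, 3 and 4.

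For differences between the lines and genes called in both, DESeq2 gave 145 for invasion, 407 for cetuximab, 1194 for the MEK inhibitor and 53 for genes called in both lines. Limma-voom with sample quality weights gave 131 for invasion, 3561 for EGF, 1002 for cetuximab, 2135 for the MEK inhibitor and 37 for genes called in both lines. Leaving out 6 doubted libraries gave 681 for cetuximab and 12 for genes called in both lines. Leaving out the shallow library gave 74 for invasion, 3120 for EGF, 472 for cetuximab, 1448 for the MEK inhibitor and 23 for genes called in both lines. The stricter filter gave 2 for genes called in both lines. The replicate block gave 1 for genes called in both lines. With a replicate left out in turn the counts were 0 to 54 for invasion, 827 to 2609 for EGF, 25 to 231 for cetuximab, 147 to 782 for the MEK inhibitor and 0 to 15 for genes called in both lines. Libraries whose absence moved a count by over 1.5 times gave, for invasion 54, 1, 0 and 0 without replicates 1, 2, 3 and 4. For EGF they gave 1027, 827 and 1067 without replicates 2, 3 and 4. For cetuximab they gave 97, 26 and 25 without replicates 2, 3 and 4. For the MEK inhibitor they gave 293, 147 and 241 without replicates 2, 3 and 4. For genes called in both lines they gave 15, 1, 0 and 0 without replicates 1, 2, 3 and 4.

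Counts of 0 came from edgeR's quasi-likelihood test, beside 488 genes at an unadjusted p under 0.05 for the 2 invasive and non-invasive Kyse30 groups alone, 170 for genes higher than in each other Kyse30 group without replicate 4, 727 and 995 for the difference between lines with invasion without replicates 3 and 4, and 149 and 161 for both lines. DESeq2 and limma-voom were not run on these reduced sets. In deviations from group means, samples of the same replicate number had a mean correlation of 0.0089 in FaDu (8 of 40 pairs above 0.1, highest 0.31). In Kyse30 it was 0.0216 (6 of 40, highest 0.35). These means pool pairs over all groups. Invasive and non-invasive samples of the same number were not examined alone, so a pairing of those is not excluded. As a block the replicate numbers moved 2 counts by over 1.5 times, those given above. The block ended the calls of 10 of 21 named genes for invasion and 8 of 93 for cetuximab in Kyse30, and of at most 5 in any other comparison. For invasion the single fit over 40 libraries ended 35 of 55 in FaDu, and in Kyse30 leaving out the 6 doubted libraries ended 9 of 21 and the fit of the compared groups alone ended 21 of 21. FaDu had no library under 1/3 of the median total, so that alternative has no value there.

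With limma-voom the share of invasion calls that were higher went from 22.0% to 46.4% in FaDu and from 16.3% to 52.5% in Kyse30, and with 1 fit over 40 libraries to 1.19% and 27.5%. In FaDu it was 36.9% with the 6 doubted libraries left out and 38.95% for the compared groups alone. With DESeq2 size factors the share of calls that were higher went in Kyse30 from 63.0% to 51.8% for non-invasive against serum-free, from 37.5% to 50.3% for cetuximab and from 36.3% to 49.2% for the MEK inhibitor against non-invasive, and with DESeq2 itself to 46.6%, 55.8% and 56.2%. The median over all genes went from -0.09 to -0.21 for invasive against serum-free, from -0.03 to 0.06 for cetuximab and from -0.02 to 0.09 for the MEK inhibitor against non-invasive, and from 0.03 to -0.08 for non-invasive against serum-free.

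Among the named genes whose sign turned, ZEB1 alone had been called. EGFR in FaDu for invasion went from -0.055 to 0.046 with the 6 doubted libraries left out and 0.036 without invasive replicate 2 (-0.10 to 0.036 with a library left out in turn). DUSP6 in FaDu for invasion went from -0.10 to 0.045 with the 6 doubted libraries left out, 0.0062 without non-invasive replicate 4, 0.026 without invasive replicate 1 and 0.035 without invasive replicate 2 (-0.27 to 0.035 with a library left out in turn). EGFR in Kyse30 for invasion went from 0.049 to -0.023 without non-invasive replicate 1 and -0.0098 without invasive replicate 2 (-0.023 to 0.17 with a library left out in turn). EGFR in FaDu for cetuximab went from -0.042 to 0.015 with the 6 doubted libraries left out and 0.028 without cetuximab replicate 2 (-0.20 to 0.028 with a library left out in turn). EGFR in Kyse30 for cetuximab went from -0.033 to 0.058 with DESeq2 size factors, 0.058 with DESeq2, 0.013 with 1 fit over 40 libraries, 0.010 without cetuximab replicate 1, 0.041 without cetuximab replicate 4 and 0.074 without non-invasive replicate 2 (-0.17 to 0.074 with a library left out in turn). DUSP6 in Kyse30 for cetuximab went from 0.35 to -0.113 without cetuximab replicate 4 (-0.11 to 0.62 with a library left out in turn). ZEB1 in FaDu for cetuximab against serum-free went from -2.42 to 0.021 without serum-free replicate 2 (-2.83 to 0.021 with a library left out in turn). DUSP6 in FaDu for the MEK inhibitor against serum-free went from 0.052 to -0.050 without MEK inhibitor replicate 2, -0.087 without MEK inhibitor replicate 4, -0.065 without serum-free replicate 2 and -0.032 without serum-free replicate 4 (-0.087 to 0.28 with a library left out in turn).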

Other observations

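The overlaps in this part were picked out after their values were seen. Effects on genes called in both lines mostly shared their direction. For non-invasive cells against serum-free spheroids 565 genes were higher and 314 lower in both FaDu and Kyse30, where independent lists would share 236.7 and 116.9, and 24 and 71 went opposite ways (one-sided Fisher's exact test for the genes higher in both, p = 2.7e-127). For cetuximab 41 were higher and 122 lower in both, where 6.72 and 17.04 were expected, and for the MEK inhibitor 70 and 215, where 23.1 and 48.9 were expected. Relative to serum-free spheroids 132 genes were higher and 66 lower in both lines with cetuximab and 152 and 80 with the MEK inhibitor.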
